A study of Homo sapiens with 4 samples.

How the data were processed

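Expression was measured in 4 samples, 1 array each, of 2 cell lines with and without TET1 knockdown. Per the labels, biotinylated cRNA was prepared with an Ambion MessageAmp kit, and the molecule was total RNA, although the extraction text of the labels describes DNA. Per the file headers, the deposited table holds a mean bead signal intensity for each of 47321 probes on each array, neither background-subtracted nor normalized between arrays. The same deposited table holds a detection p-value per probe, which falls in steps that fit 770 negative control probes per array. A second deposited table holds values on a log2-like scale made by the authors with lumi, per the submitters' processing notes. The lumi version, transformation and normalization are not given in the sources used here. Set against the log2 raw signal of the same array, these deposited values had a slope between 0.974 and 1.08 where the log2 signal was at least 11 and between 0.333 and 0.381 where it was below 7.2, with medians of 8.28, 8.30, 8.30 and 8.28 on the 4 arrays. They are thus flatter near background than log2 values, and the transformation stays unknown. All per-sample columns matched a sample.

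The raw intensity was background-corrected by normexp with negative controls inferred from the detection p-values, an offset of 16 was added, and arrays were quantile normalized and log2 transformed (neqc in limma 3.58.1, R 4.3.3). A probe was called detected at a detection p under 0.01. Gene symbols came from the deposited table and were updated through RefSeq names of GRCh38.p14, used for names only. Of 31397 distinct symbols, 17761 were current, 3283 were renamed through a unique synonym and 10353 were kept as given. Another 3270 probes had no symbol and 54 had one turned into a date, and these were left out of gene tables. Each of 30908 genes was represented by its probe with the highest mean signal.

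Within a line a gene counted as changed if its normalized values differed at least 2-fold and it was detected on at least 1 of the 2 arrays. There is no test within a line. A gene undetected on 1 side has only a bound, written as at least N-fold, against the lowest normalized value of detected probes on that array or its own value where higher. In differences between lines, each undetected array was held the same way. No fold is given where both sides were below background or the bound was under 1. Across lines, limma fitted line and knockdown to 12965 genes detected on at least 2 arrays, with an intensity trend, 1 residual degree of freedom and Benjamini-Hochberg adjustment at 0.05, two-sided. The estimated prior degrees of freedom were infinite, so each standard error follows the trend over all genes. A limma p-value thus sets a gene's change against the usual disagreement of the lines at its signal level, not against the gene's own spread. The labels do not say whether arrays came from separate cultures, so no p-value extends beyond these samples.

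There were 25 gene lists, written before the data were examined. Within a line, a list's median change was placed among 10000 random lists of the same size drawn from 20 bins of mean expression (matrixStats 1.5.0). Across lines, lists were tested by camera, which sets a list's members against other genes, with a preset correlation of 0.01. An estimated correlation and fry were alternatives. With an estimated correlation, camera refers its statistic to the 1 residual degree of freedom of this fit, which leaves it little power to call any list. Agreement of probes of a gene was measured as an intraclass correlation, with 95% intervals from 1000 bootstrap draws of genes. Figures were drawn with matplotlib 3.10.9.

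Named genes followed a rule fixed before the data were examined. It took TET1 with every probe, the 10 largest changes each way in each line, the 10 largest shared changes each way, the 10 largest line differences each way, up to 4 members of each list past its bounds, and CDKN1A, MDM2, TET2, TET3, DNMT1, DNMT3A and DNMT3B. Some items that the rule or the lists name are not reported here. ACTB and GAPDH were chosen after their values were seen.

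On simulated data with 200 of 12965 genes changed and the noise of these arrays, the test across lines recovered 0.5% of genes changed 2-fold, 16% at 4-fold, 88% at 16-fold and 100% at 64-fold. With noise simulated well below that, it recovered 84.5% of genes changed 2-fold. In simulated lists, 17 of 20 lists shifted 2-fold passed the percentile bounds in A549, with 1 of 20 unshifted lists, and camera called 11 of 20 lists shifted 1.41-fold across lines and 0 unshifted. Simulated genes had independent noise and the lists were random. Members of real lists can move together. Their estimated correlation, rough at 1 residual degree of freedom, was 0.23 for interferon response and 0.33 for histone genes. The simulation therefore does not give the rate of false calls among real lists. Alternatives were the deposited values, no background correction, an offset of 50, median centring, normalization within each line, other detection filters, the mean of a gene's probes, a 1.5-fold threshold, other forms of the limma fit and other list tests. Using the least bright detected probe, and centring on the median change, were chosen after seeing the data.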

Results

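Gene expression was measured on 4 Illumina bead arrays hybridised with labelled cRNA from total RNA of 2 human lung cancer cell lines, A549 and H1299. A549 is a lung adenocarcinoma line, and H1299 is a non-small cell lung cancer line derived from a lymph node metastasis. Each line gave 1 array of cells in which TET1 had been knocked down by siRNA and 1 array of the parent line given vehicle. TET1 is a dioxygenase that oxidises 5-methylcytosine in DNA. The design asks which transcripts differ after loss of TET1 and whether the lines share them. No group had a replicate, so within a line no difference has a measured error, and across lines the spread is the disagreement between the 2 lines. Of 47321 probes, 13980 were detected in the A549 control, 17107 in the A549 knockdown, 16883 in the H1299 control and 14417 in the H1299 knockdown. Precision is limited by the number of arrays.

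The targeted gene was lower in both knockdowns, close to the detection limit. On the TET1 probe ILMN_3247163 the raw signal was 222.1 in the A549 control and 164.5 in the A549 knockdown, and 255.9 and 186.8 in H1299. The array software's detection value for this probe was 0.0013 in both controls, 0.0805 in the A549 knockdown and 0.0169 in the H1299 knockdown, so that it was detected in the controls alone. Normalized TET1 signal was at least 3.06-fold lower in A549 (log2 change -1.95) and at least 1.72-fold lower in H1299 (log2 change -0.90). The mean TET1 change over the lines was -1.42 ± 0.93 (SE) on the log2 scale, with undetected values taken as read, which limma did not separate from 0 (unadjusted p = 0.126). That SE follows the usual disagreement of the lines, so the test could hardly separate a change of this size. By the smaller of its changes in the lines, read the same way, TET1 ranked 15 from the lowest of 11751 genes. A second TET1 probe, ILMN_1741056, was detected only in the H1299 control, at a raw signal of 182 against 137.5 in the H1299 knockdown. On the deposited values the TET1 changes were -0.28 and -0.11. The related genes TET2 and TET3 and the de novo methyltransferase DNMT3A were below background on all arrays. DNMT1, the maintenance methyltransferase, changed by -0.06 in A549 and 0.22 in H1299, and DNMT3B by 0.07 and -0.49. The other DNMT3B probes detected on all arrays disagreed in H1299, ILMN_2328977 changing by 0.31 and 0.95 and ILMN_1794692 by 0.05 and -0.25.

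For ACTB and GAPDH, chosen after their values were seen, some probes read differently on the A549 control and H1299 knockdown arrays than on the other 2 arrays. For the beta-actin gene ACTB, probe ILMN_1777296 was at least 41.6-fold higher in the A549 knockdown than in its control and at least 195-fold lower in the H1299 knockdown than in its control, undetected on the lower side each time. The other ACTB probes, ILMN_2152131 and ILMN_2038777, changed by -0.71 and -1.85 in A549 and by -0.83 and -1.51 in H1299. Probes of GAPDH, a glycolytic enzyme, also disagreed. Its probe ILMN_2038778 changed by 1.92 and -1.69 in A549 and H1299, ILMN_1343295 by 1.62 and -1.26, and ILMN_1802252 by -0.11 and 0.38. The last of these changes in A549 was 0.02 when arrays were centred on their medians. No other scaling turned the direction of an ACTB or GAPDH probe.

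**Figure D1:**
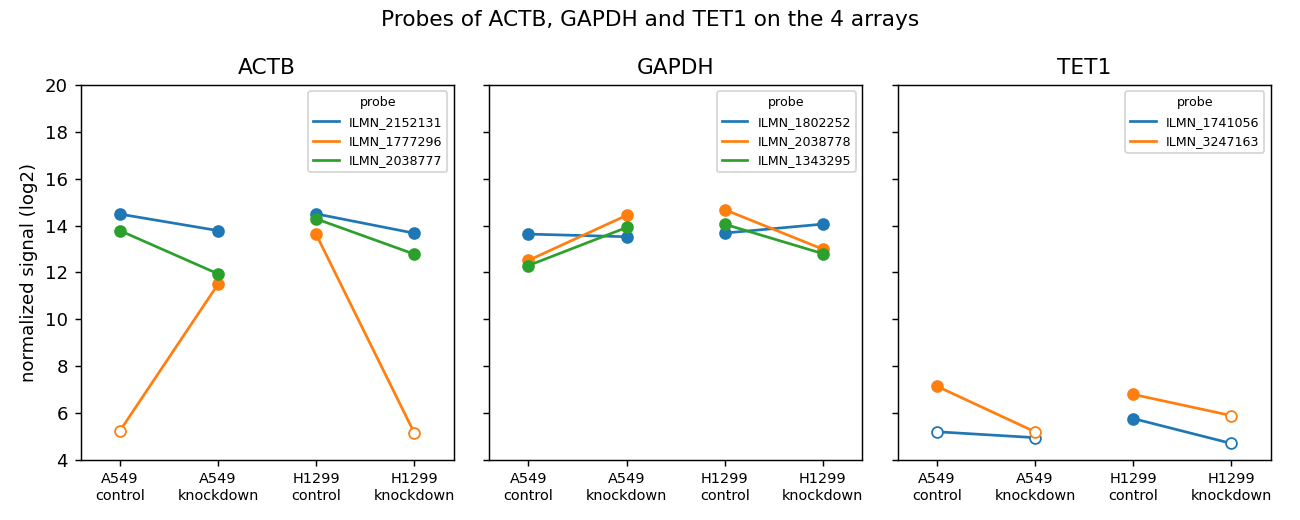
Normalized signal (log2, vertical axis) of each probe of ACTB, GAPDH and TET1 on the 4 arrays (horizontal axis). Lines join the 2 arrays of a cell line, and open circles mark probes not detected at p under 0.01. ACTB probe ILMN_1777296 was at least 41.6-fold higher in the A549 knockdown and at least 195-fold lower in that of H1299, and the other ACTB probes were lower in both knockdowns.

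Across both lines, 1 transcript passed the test of knockdown against control. The uncharacterised transcript LOC100132564 was higher by 7.47 ± 0.77 (SE) log2 units over the lines (limma adjusted p = 2.62e-18), with its undetected A549 control taken as read, and by at least 6.84 with that array at its floor. With median centring 0 transcripts passed, the prior degrees of freedom then being 3.2, and 0 with no block for line. LOC100132564 was at least 106-fold higher in A549 and 124-fold higher in H1299. No transcript passed in the lower direction. In limma, 23 of 12965 genes had an unadjusted p under 0.05, against 648.25 that chance alone would give if the p-values were uniform. The error of this fit is the disagreement of the lines, and so holds the change by which they opposed each other. Over genes that opposing change had a standard deviation of 0.919, against 0.385 for the mean change. The p-values therefore run large, and failing this test says little about whether a change is shared. By normalized change of at least 2-fold in each line, 8 genes were higher in both knockdowns and 9 were lower in both; with undetected sides held at their bound, 4 and 7 were.

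The genes with the largest shared increases, apart from LOC100132564, follow. GDF15, a secreted cytokine of the TGF-beta superfamily, was 4.88-fold higher in A549 and at least 2.16-fold higher in H1299. The 5S ribosomal RNA gene RNA5S9 was at least 1.39-fold higher in A549 and 17.4-fold higher in H1299. FTH1P3, a ferritin heavy chain pseudogene that is nearly identical to FTH1 and so uncertain, was 2.24-fold and 3.5-fold higher. TOX2, a transcription factor, was 3.03-fold and 2.59-fold higher, and the complement component C5 was 1.98-fold and 2.09-fold higher. CIT, a kinase of cytokinesis, was at least 1.42-fold higher in A549 and 2.66-fold higher in H1299. LOC100008588 was at least 7.6-fold and at least 1.86-fold higher, and LOC643015 at least 1.17-fold and at least 1.79-fold. The hyaluronan-binding protein gene CEMIP was 2.04-fold higher in H1299, and too near background in the A549 control for a fold.

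Among the largest shared decreases, IGFBP3, which binds insulin-like growth factors, was 3.21-fold lower in A549 and 2.02-fold lower in H1299. SLC39A14, a zinc and iron transporter, was 2.05-fold and 5.32-fold lower. The dynein light chain gene DYNLT3 was 7.17-fold and 2.64-fold lower. ALG10B, a glucosyltransferase of N-glycan assembly, was 2.2-fold and 4.28-fold lower, although its mean change was 0.12 when its least bright detected probe stood for the gene. The small nucleolar RNA genes SNORA67 (2.35-fold and 2.67-fold) and SNORA62 (1.97-fold and at least 2.43-fold) were lower in A549 and H1299. MIR1974 was 3.38-fold and at least 2.39-fold lower, LOC644936 12.2-fold and 2.02-fold, and LOC731007 2.33-fold and at least 1.92-fold. MEX3B, an RNA-binding protein gene, was 2.62-fold lower in A549 and too near background in H1299 for a fold. None of these passed the test on its own, with an adjusted p of 0.999961 or more in limma. Since that test takes the disagreement of the lines as its error, this does not show that the changes are not shared.

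**Figure D2:**
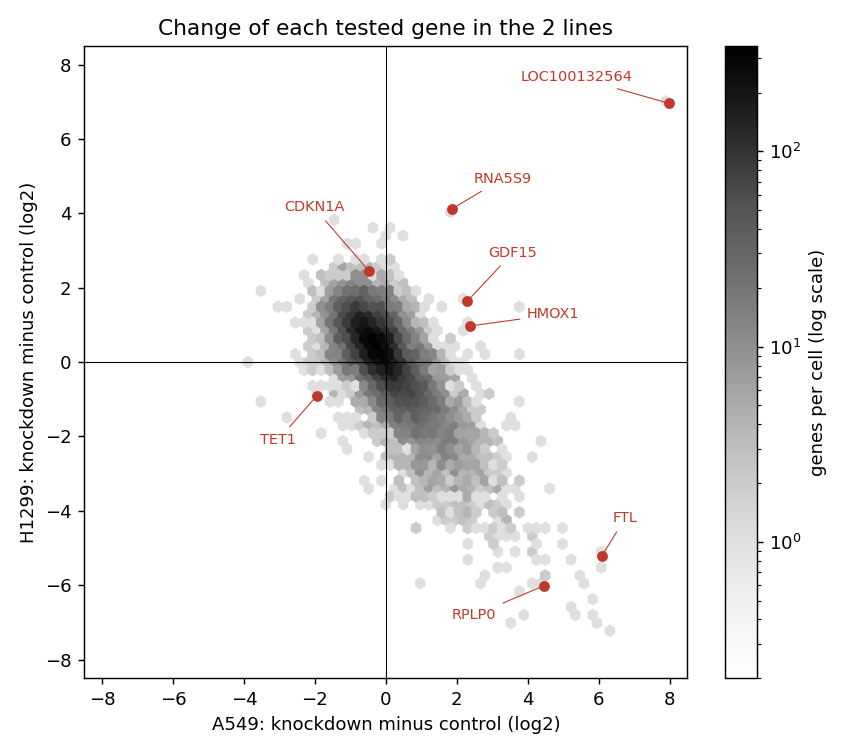
Knockdown minus control (log2) of each of 12965 tested genes in A549 (horizontal axis) and H1299 (vertical axis), with darker cells holding more genes on a log scale and named genes in red. The cloud runs from upper left to lower right (Pearson r = -0.726), LOC100132564 stands alone at upper right, and TET1 lies at lower left.

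Over the lines, targets of NRF2, the regulator of antioxidant enzymes, passed the list test in the upward direction. The median mean change of its 31 tested members was 0.33 on the log2 scale (limma camera adjusted p = 9.52e-07), with 11 members higher in both lines and 1 lower in both. Taken alone, the list lay above random lists in A549 and within their central 95% in H1299 (median 0.53, 19 of 28 members higher, percentile 96.68). Its members FTL (68.2-fold higher in A549 and 36.9-fold lower in H1299) and PGD (4.96-fold higher and 8.92-fold lower) changed in opposite directions. The call was lost with an estimated correlation (adjusted p = 0.593), as were the calls of the interferon and histone lists. HMOX1, the inducible heme oxygenase, was 5.21-fold higher in A549 and 1.96-fold higher in H1299. The ferritin heavy chain gene FTH1 was 1.37-fold and 3.35-fold higher. OSGIN1 was 1.02-fold and 3.61-fold higher, although its second detected probe changed by -0.69 in H1299, and the glutathione peroxidase GPX2 was 4.05-fold higher in A549 and below background in H1299. Interferon response genes (36 members, median 0.26, adjusted p = 0.0106, 6 higher in both) and histone genes (20 members, median 0.37, adjusted p = 0.0175, 4 higher in both) also passed in the upward direction, although in A549 their medians were -0.16 (13 of 34 members higher) and -0.34 (5 of 18 higher). IFI35 was 1.2-fold higher in A549 and 3.26-fold in H1299, and IFI44 was 3.4-fold higher in H1299. The histone gene H2BC5 was 1.39-fold lower in A549 and 5.88-fold higher in H1299, although another probe, undetected on 1 of the 2 A549 arrays, changed by 0.70 in A549.

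In the downward direction 8 lists passed, each with the preset correlation alone (adjusted p = 0.593 for each with an estimated correlation). Changes were larger in H1299 (standard deviation over genes 1.12) than in A549 (0.855), so a mean over the lines can follow H1299. A call over the lines is therefore not by itself a change shared by both. Cholesterol synthesis genes had a median mean change of -0.35 over 24 members (adjusted p = 0.00107), with 9 lower in both lines and 1 higher in both. In A549 alone their median was -0.16, at percentile 46 of random lists, with 10 of 24 members higher. Among the cholesterol genes the desaturase SCD was 1.88-fold lower in A549 and 1.71-fold lower in H1299, and INSIG1, a sterol sensor, was 1.25-fold and 3.01-fold lower. DNA replication genes (32 members, median -0.12, adjusted p = 0.0188) had 8 lower in both and 0 higher in both. Their median in A549 alone was -0.17, at percentile 41 of random lists, with 12 of 32 members higher. The cyclin gene CCNE2 was 1.17-fold higher in A549 and 5.18-fold lower in H1299, and the licensing factor CDC6 was 2.22-fold lower in A549. MYC targets and ribosome biogenesis genes (28 members, median -0.11, adjusted p = 0.0188; median 0.05 in A549, 16 of 28 higher) included MYC itself, 1.48-fold higher in A549 and 3.74-fold lower in H1299, and GNL3, 1.08-fold and 2.09-fold lower, with a second probe that changed by 1.23 in A549. Cytosolic ribosomal proteins (44 members, median -0.07, adjusted p = 0.0335) had 4 lower in both and 5 higher in both. In A549 alone they lay above random lists (median 0.03, percentile 98.24). Mesenchymal genes (17 members, median -0.32, adjusted p = 0.0229) had 6 lower in both, and their member ZEB2 was at least 1.67-fold lower in A549 and 2.22-fold lower in H1299. Cancer-testis genes (17 members, median -0.08, adjusted p = 0.0229) included MAGEA6, 1.62-fold and 2.35-fold lower, and MAGEA4, 1.79-fold lower in H1299. HOX genes (22 members, median -0.17, adjusted p = 0.0486) had 7 lower in both, but their median in H1299 was 0.25 with 13 of 21 higher, and HOXC4 was 1.14-fold and 2.62-fold lower. The list of lung alveolar and airway markers had 4 tested members (median -0.51, adjusted p = 0.00799), among them CAV1 at 1.01-fold higher and 2.53-fold lower.

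Of these 11 lists, fry called none (adjusted p = 0.921 for each). Over 11 settings NRF2 targets kept their call in 9, cholesterol synthesis, DNA replication and interferon response genes in 8, histone genes and MYC targets in 7, cancer-testis genes and lung markers in 6, HOX genes and ribosomal proteins in 5 and mesenchymal genes in 4. No member of any list passed over the list alone. Senescence regulators (median 0.08, adjusted p = 0.314) and mitosis genes (median -0.02, adjusted p = 0.39) did not pass. CDKN1A, the p21 inhibitor of cyclin-dependent kinases, was 1.39-fold lower in A549 and 5.46-fold higher in H1299, a mean of 0.99 ± 0.62 (SE; limma unadjusted p = 0.114). MDM2, a ubiquitin ligase gene, was near background on all arrays.

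In A549, 2600 of 13228 detected genes (19.7%) differed at least 2-fold by normalized change, 1453 higher and 1147 lower in the knockdown, and 2096 did with undetected sides at their bound. The split was 2744 higher and 184 lower with median centring, and 399 and 116 on the deposited values. With 1 array per group there is no test of these. The largest increases were the ferritin light chain FTL (68.2-fold), the elongation factor EEF1G (60.4-fold) and the glycolytic enzyme PGAM1 (at least 23.5-fold), besides LOC100132564 and the transcripts LOC728698, LOC644743, LOC649150, LOC388654, LOC387867 and LOC729926. Each of these apart from LOC100132564 was lower in the H1299 knockdown. The largest decreases included SLN, a sarcoplasmic reticulum calcium pump regulator (14.7-fold), LOC644936, the chorionic gonadotropin gene CGB1 (11.1-fold), LOC645638 (7.59-fold), DYNLT3, LOC100132288 (6.81-fold), KANK4 (6.26-fold), the small heat shock protein CRYAB (at least 6.15-fold) and the lysophosphatidic acid receptor LPAR5 (at least 3.42-fold).

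Set against 10000 random lists of like expression, 6 lists lay above the central 95% in A549 and 1 below it. The median change of all detected genes was -0.13, and 0.32 when arrays were centred on their medians. NRF2 targets (median 0.38, 100th percentile) had 22 of 31 members higher, EPHX1 at least 4.88-fold. Heat shock genes (median 0.40, percentile 99.96) had 15 of 19 members higher, among them the chaperone genes STIP1 (12-fold), DNAJB1 (7.73-fold) and HSPA1B (3.38-fold). Epithelial genes (median 0.84, percentile 99.94) had 12 of 17 higher, with the junction genes JUP at least 9.58-fold and DSP 3.82-fold and the keratin KRT19 5.86-fold. Another DSP probe, undetected on 1 of the 2 arrays, changed by -0.08. The integrated stress and unfolded protein response list (median 0.15, percentile 98.6) had 16 of 30 higher, with EDEM1 at least 2.71-fold and the amino acid transporter SLC7A5 2.22-fold, and was past the bounds in 5 of 9 settings (percentile 92.8 to 98.67). Secreted senescence factors (median 0.29, percentile 97.8) had 14 of 25 higher, with IGFBP6 13.6-fold and the chemokine CXCL5 4.3-fold, but were past the bounds in only 3 of 9 settings (percentile 69.2 to 99.1). Cytosolic ribosomal proteins (median 0.03, percentile 98.2) had 24 of 44 higher and kept the call in 8 of 9 settings. Relative to all genes their median was 0.16, and -0.28 with median centring. Mesenchymal genes (median -0.55, percentile 1.39) had 3 of 16 higher, with the collagen COL1A1 4.39-fold lower and the matrix protein SPARC 3.71-fold lower, but were past the bounds in only 3 of 9 settings (percentile 0.06 to 68.25). Among A549 genes past 2-fold with at least 2 detected probes, 169 of 435 had every probe past 2-fold and 111 had a probe of the opposite sign.

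In H1299, 4388 of 13207 detected genes (33.2%) differed at least 2-fold by normalized change, 2443 higher and 1945 lower, again with no test, and 3829 did with undetected sides at their bound. The split was 779 higher and 3118 lower with median centring, and 416 and 691 on the deposited values. The largest increases after LOC100132564 and RNA5S9 were the microfibril gene MFAP5 (15.1-fold), the channel gene PANX2 (12.1-fold), DPEP3 (11.9-fold), the neurotensin receptor NTSR1 (11-fold), the lysyl oxidase LOX (9.22-fold), the splicing factor HNRNPH1 (at least 8.79-fold, although 2 other probes, each undetected on 1 of the 2 arrays, read lower), LY96 (at least 6.58-fold) and ECM1 (at least 5.89-fold). The largest decreases included LOC649150 (137-fold), LOC100133372 (125-fold), MORF4L2 (at least 86.4-fold), EEF1G (at least 84.6-fold), PGAM1 (at least 62.2-fold, a second detected probe changing by -2.85), the mitochondrial ribosomal protein MRPS35 (at least 45.2-fold), LOC92755 (at least 28.8-fold) and MAEA (at least 23.4-fold), with LOC728698 and LOC729926.

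In this line 2 lists lay above the central 95% of random lists and 7 below it. The median change of all detected genes was 0.28, and -0.12 with median centring. Histone genes (median 1.004, percentile 99.98) had 18 of 22 members higher, with H2AC18 8.83-fold (another probe, undetected on 1 of the 2 arrays, did not read higher) and H3C4 at least 5.16-fold. Interferon response genes (median 0.82, percentile 99.8) had 26 of 36 higher, with IRF1 5.64-fold, IFI6 4.3-fold (its second detected probe changed by 0.29) and ISG20 4.07-fold. All 5 leukocyte markers detected were higher too (median 1.11, percentile 94.9, within the central 95%). Epithelial genes (median -1.59, percentile 0.08) had 4 of 9 members higher, and TJP1, a tight junction protein, was 12.3-fold lower. That list was past the bounds in 5 of 9 settings (percentile 0.07 to 15.23), with a median of -0.20 on the deposited values and -0.62 without background correction, and JUP, DSP and ELF3 were undetected in the knockdown, with bounds of at least 1.28-fold, 1.62-fold and 1.25-fold lower. MYC targets (median -0.35, percentile 0.1) had 9 of 29 higher, with CAD 7.06-fold and DDX21 4.81-fold lower. Cholesterol synthesis genes (median -0.54, percentile 0.11) had 6 of 26 higher, with DHCR7 5.69-fold and EBP 5.5-fold lower. DNA replication genes (median -0.25, percentile 0.13) had 12 of 32 higher, with MCM5 5.88-fold and TYMS 3.66-fold lower. Cytosolic ribosomal proteins (median -0.04, percentile 0.28) had 21 of 44 higher, and RPS2 was 36.4-fold lower. Heat shock genes (median -0.26, percentile 0.52) had 5 of 19 higher, with DNAJB1 24.8-fold and STIP1 20.8-fold lower. Cancer-testis genes (median -0.33, percentile 2.05) had 6 of 16 higher, and MAGEA3 was 3.49-fold lower; they were past the bounds in 6 of 9 settings (percentile 0.76 to 28.55). HORMAD1 was 2.09-fold lower, but changed by 0.16 on the log2 scale when its least bright detected probe stood for the gene. Of 922 genes past 2-fold with at least 2 detected probes, 357 had every probe past 2-fold and 332 had a probe of the opposite sign.

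**Figure D3:**
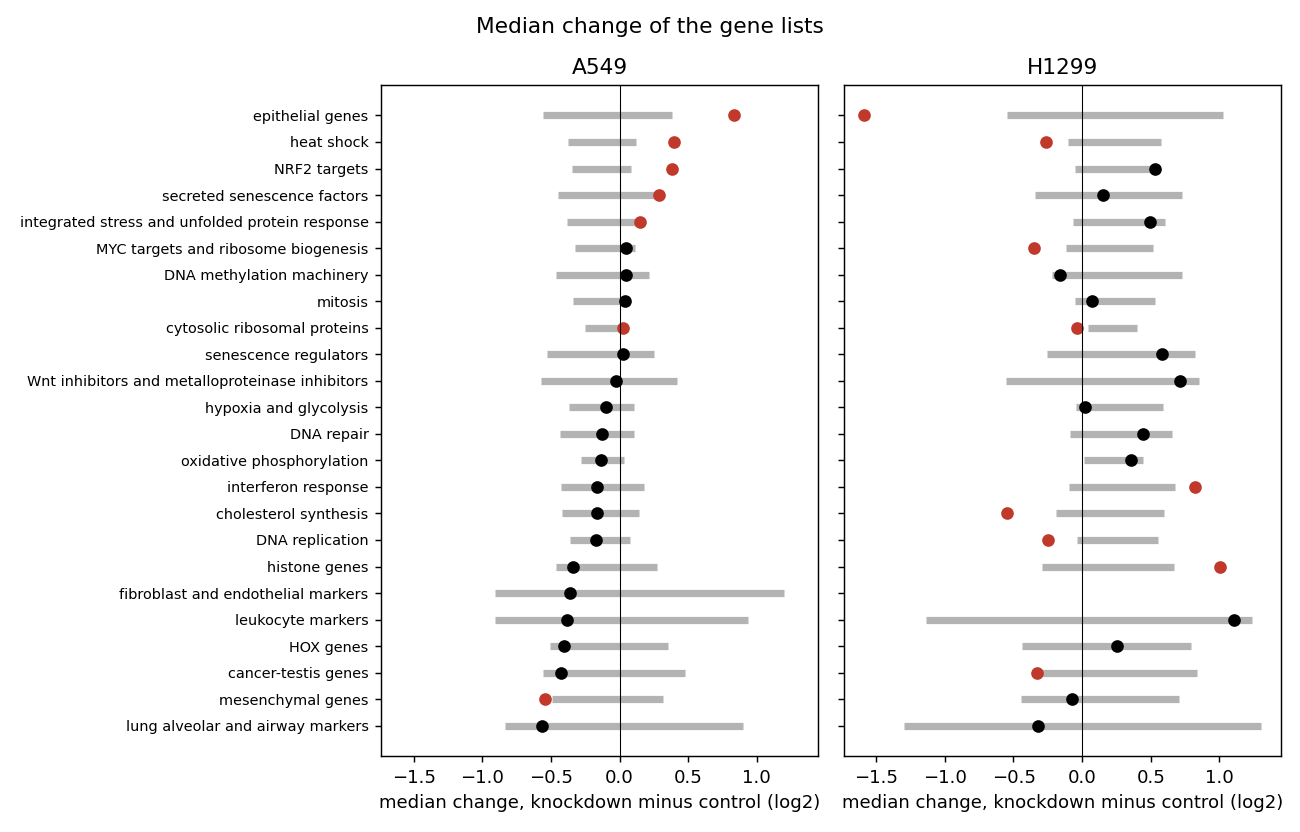
Median change, knockdown minus control (log2, horizontal axis), of the gene lists in A549 and H1299. Grey bars span the central 95% of 10000 random lists matched on expression, and red points lie outside them; no fibroblast or endothelial marker was detected in H1299. Epithelial genes (0.84 and -1.59) and heat shock genes (0.40 and -0.26) lie outside in opposite directions in the 2 lines.

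The changes of the 2 lines opposed each other across genes. Over 12965 genes the Pearson correlation was -0.726 and the Spearman correlation -0.657. Genes are not independent replicates, so no p-value is attached. The changes had opposite signs for 77.5% of genes, while 13.4% were higher in both lines and 9.01% lower in both. By normalized change of at least 2-fold each way, 975 genes were higher in A549 and lower in H1299, and 538 were the reverse. The 2 pairs of arrays shared no control.

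Between the lines, 651 genes differed in limma with knockdown as the other term (adjusted p under 0.05), 220 higher in H1299 and 431 higher in A549. With median centring 0 did, and 296 on the deposited values. The 10 highest in H1299 were all GAGE cancer-testis antigen genes, and 9 of them were below background on both A549 arrays. GAGE12C was at least 659-fold higher (limma adjusted p = 1.48e-35), and near-identical family members can share probes, so individual GAGE genes are uncertain. Higher in A549 were KRT81, a hair keratin (207-fold), the aldo-keto reductase AKR1B15 (at least 229-fold), the kynureninase KYNU (at least 236-fold), the insulin-like growth factor binding protein IGFBP4 (at least 223-fold), the vitamin D hydroxylase CYP24A1 (at least 111-fold), MALL (at least 118-fold), the transcription factor FOXA2 (at least 106-fold), RSPO3 (at least 104-fold), the carbonic anhydrase CA12 (at least 105-fold) and S100A4 (at least 95.8-fold).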

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

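The tests of explanations in this part were all chosen after the results they bear on were seen. The differences below were not tested, since each line has 1 array per group. They are listed because the single knockdown array of A549 moved one way and that of H1299 the other, by a normalized change of at least 2-fold each for genes.

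The values for genes are differences of normalized changes, which take an undetected side as it was read. Of the 45 genes, 27 were measured in both lines and 15 have only a bound in a line, so their differences are not folds. Among the latter the H1299 decrease is shown only as at least 1.28-fold for JUP, 1.62-fold for DSP, 1.25-fold for ELF3 and 1.24-fold for EDEM1. For 3 genes a line gives no fold: MAEA and RRP9 in A549 and IGFBP6 in H1299, so an opposite change is not shown for them.

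Among gene lists, the median change in A549 minus that in H1299 was 2.43 on the log2 scale for epithelial genes, 0.66 for heat shock genes and 0.0640 for cytosolic ribosomal proteins. The epithelial medians rest on 17 members detected in A549 and 9 in H1299. They were 0.25 and -0.20 on the deposited values and 0.48 and -0.62 without background correction, so the size of that difference depends on the processing. For the transcripts higher in A549 and lower in H1299 by normalized value, the same difference was 13.57 for LOC728698, 13.02 for LOC649150, 12.54 for PGAM1, 12.35 for EEF1G, 11.98 for LOC729926, 11.74 for MRPS35, 11.59 for LOC644743, 11.46 for LOC388654, 11.30 for FTL, 11.08 for LOC387867, 10.65 for MORF4L2, 10.59 for LOC100133372, 9.91 for LOC92755 and 7.07 for MAEA. Ribosomal protein genes showed 10.48 (RPLP0), 9.44 (RPS2), 5.33 (RPS9) and 3.68 (RPS3), and heat shock genes 7.96 (STIP1), 7.58 (DNAJB1), 4.31 (HSPA1B) and 3.27 (HSPA4L). Values were 5.21 for JUP, 3.61 for DSP and 3.26 for ELF3 among epithelial genes, 5.47 for PGD, 5.18 for PDIA6, 3.45 for EDEM1, 2.69 for SLC7A5 and 4.81 for IGFBP6. They were 4.76 for MCM5, 4.31 for DHCR7, 4.21 for EBP, 5.20 for CAD, 3.32 for DDX21 and 3.16 for RRP9. In the opposite sense, lower in A549 and higher in H1299, the difference was -5.37 for MFAP5, -5.30 for CGB1, -4.44 for LOC645638, -4.35 for LOC100132288, -4.35 for H2AC18, -3.82 for IFI6, -3.75 for RHOU, -3.71 for IRF1 and -3.47 for ABCA3.

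The changes of the 2 lines opposed each other across genes (r = -0.726). Regulation of whole genes in opposite directions is argued against as the whole cause, because probes of a gene shared little of the opposing change: the intraclass correlation was 0.224 (95% interval 0.187 to 0.262), against 0.805 for the difference between lines. For the mean change over the lines it was 0.251 (95% interval 0.215 to 0.287), so probes of a gene shared little of that change either. The same limit therefore holds for changes shared by the lines. A candidate explanation is that the A549 control and H1299 knockdown arrays read single probes differently from the other arrays, as from RNA quality or labelling. Fewer probes were detected on these arrays (13980 and 14417) than in the A549 knockdown (17107) and H1299 control (16883), which does not name a cause. Deviations of probes from their own gene's mean change correlated at -0.798 between the lines (95% interval -0.813 to -0.781). A strongly negative value follows largely from the opposing changes and the low intraclass correlation, so it is not separate support. What would have made the arrays differ is open, since probe positions along transcripts were not used here. An exchange of the H1299 control and knockdown arrays cannot be told apart from the labelled order, since the TET1 change of -0.90 there lies near the floor. The second TET1 probe ran the same way as the labels, from a raw signal of 182 in the control to 137.5 in the knockdown, but neither probe was detected on both arrays.

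NRF2 targets passed the list test across the lines in the upward direction. Against random lists they lay above the central 95% in A549 (median 0.38). In H1299 they lay just within it (median 0.53, upper bound 0.54, percentile 96.68). The lines were not tested against each other, so a response of A549 alone is not shown. A few ferritin or aldo-keto reductase probes are argued against, since without FTL, FTH1 and the AKR1 genes the list's p was 5.75e-08. A shift of bright genes is argued against too, as the list's median lay at the 100th percentile of random lists matched on level. Another explanation is an opposing array difference that did not cancel between the lines. With the trend of the mean change on the opposing change removed, the list's median stayed at the 100th percentile. That trend held only 13.8% of the variance of the mean change and cannot carry differences of single probes, so the array difference stays open. It was not examined for the other lists called across the lines and stays open for them too. A response to siRNA transfection cannot be told apart from loss of TET1, because the controls had vehicle and no array had a non-targeting siRNA. The 11 of 31 members higher in both lines do not decide between these. The call also depends on the form of the list test, being lost in camera with an estimated correlation (adjusted p = 0.593). That estimate, from 1 residual degree of freedom, was -0.00645 for this list, against the preset 0.01. This form of camera refers its statistic to the same 1 degree of freedom. It thus has little power, and losing the call there decides nothing about the list.

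CDKN1A was 5.46-fold higher in the H1299 knockdown and 1.39-fold lower in A549. Given its A549 change, its H1299 change lay at percentile 99.7 of 648 genes of like level, and at percentile 99.85 without regard to A549, so the first value adds little to the size of the change, and the array difference cannot be told apart as its cause. The gene rests on 1 detected probe, so a probe-specific array effect cannot be told apart from a higher transcript level. The loss of TET1 stays among the open explanations, untested.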

How the results depend on the processing

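The settings with the least bright detected probe and with changes centred on the median were chosen after seeing the data. No replicate could be left out, since each group had 1 array, and leaving out either doubted array would remove its comparison. The main fit across lines has the line as a block. The count of A549 genes past 2-fold was 515 on the deposited values, 881 without background correction, 1648 with an offset of 50 and 5715 at 1.5-fold; under the remaining settings it lay between 2106 and 3081. For H1299 it was 1107, 1912 and 7738 for the first, second and last of these, and otherwise between 3206 and 4921. The TET1 change in A549 was -0.28 on the deposited values, -0.76 without background correction and -1.31 with an offset of 50; in H1299 it was -0.11 on the deposited values and -1.63 with median centring. The deposited scale compresses dim signal (slope 0.333 to 0.381 near background); whether this or another setting's feature caused these differences was not tested. The split of genes past 2-fold moved with scaling: 55.9% were higher in A549 and 55.7% in H1299, against 93.7% and 19.99% with median centring, 77.5% and 37.6% on the deposited values, 73.4% and 43.3% without background correction, and 69.7% and 33.8% with changes centred on the median. Genes differing between lines numbered 296 on the deposited values, 390 with the least bright probe and 0 with median centring, where the prior degrees of freedom were 3.2 and not infinite. Genes changed across lines numbered 0 with median centring and 0 with no block, where the line difference stays in the error; under the other settings run 1 passed. Lists past the bounds in A549 numbered 4 without background correction. Lists changed across lines numbered 1 with no detection filter, 0 with an estimated correlation and 0 with fry, and 8 to 11 otherwise. With an estimated correlation camera had only 1 degree of freedom and little power, and the cause was otherwise not tested. The correlation of changes stayed between -0.643 and -0.758. Against the report, 2 named values reversed with the least bright probe: the ALG10B mean change was 0.12 and the HORMAD1 change in H1299 was 0.16. Of the other named gene values over the settings, 1447 moved by less than 1.5-fold and 358 moved more. The first number includes 203 values with the looser detection filter and 203 with no filter. Neither setting could move a named value, since it is computed before the filter. A reversal was counted only for a change of at least 2-fold, so reversals of smaller changes are not counted. Across lines, list calls were kept in 9 of 11 settings for NRF2 targets, 6 for cancer-testis genes and lung markers, 5 for HOX genes and ribosomal proteins, 4 for mesenchymal genes, and 7 or 8 for the others.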

Other observations

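Small RNA genes and the ribosomal RNA gene RNA5S9, chosen by symbol after their values were seen, were counted by direction. Transcripts without such a symbol were not counted, so the count does not describe ribosomal RNA. Leaving out 4 host-gene transcripts, 98 such genes were detected in both lines. By normalized change, 29 (29.6%) were lower in both, 8 (8.16%) were higher in both and 61 changed in opposite directions. Over all genes detected in both lines, 8.26% were lower in both and 12.5% higher in both. No test was run on this difference. RNY4, a Y RNA, changed by -2.01 in A549 and -0.55 in H1299, and the small Cajal body RNA SCARNA13 was at least 2.58-fold lower in A549 and 1.74-fold lower in H1299. RNA5S9 went the other way, at least 1.39-fold and 17.4-fold.

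NQO1, the quinone reductase often read as a marker of NRF2 activity, was chosen after its values were seen. Its brighter probe changed by 0.17 in A549 and 0.58 in H1299, and its second detected probe, ILMN_2354953, by 1.65 and 1.31. Secreted senescence factors had the smallest fry p of the 25 lists (0.00376, adjusted 0.0939), with 6 of 22 tested members higher in both lines and 2 lower in both, and camera did not call them (adjusted p = 0.355). LMNB1, the lamin B1 gene whose level falls in senescent cells, changed by -0.56 and -0.79, chosen after its values were seen. The list of senescence regulators that holds it did not pass (camera adjusted p = 0.314). That list had 4 members higher in both lines and 2 lower in both, so LMNB1 does not stand for it.

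For the mean change over the lines, the intraclass correlation of probes of a gene was 0.251 (95% interval 0.215 to 0.287) over 6206 probes of 2847 genes. For the opposing change it was 0.224 (0.187 to 0.262), and the difference between them was not tested. The standard deviation of the mean change over genes was 0.385, and that of the opposing change 0.919. Among 3324 unnamed probes, 1017 were detected on at least 1 array, and 0 were at least 2-fold higher, or lower, in both lines.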
